A study of Mus musculus with 24 samples.

How the data were processed

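Per the labels' protocols, brown adipose tissue was extracted with TRIzol and the RNeasy lipid mini kit, and libraries were made from polyA-selected RNA. The labels name cutadapt 1.9.1 and GSNAP 2013-11-27 without stating their roles. The genome build, annotation, read counter and strandedness were not given in the sources used here, so no coordinates are given. The values as deposited covered 23017 genes and were taken to be log2 values, rolled up to genes and quantile normalized by the authors. This scale was inferred from the values: sorted libraries were nearly identical, as after quantile normalization, and the most common low values became near-even steps when read as log2 with an offset of 1. Values ran from -0.50 to 22.35, so the offset does not hold exactly for every value. An offset near 1 would understate fold changes of weakly expressed genes. The number of reads per library is unknown, and the most frequent low value above 0, taken as that of 1 read, served as a proxy of depth. Less frequent levels lay below it, as fractions of a read would give.

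The quantiles of the libraries were close to equal (the 25% quantile from 2.88 to 2.95, the 75% quantile at 6.21), and the values were used without further normalization. The 25% of genes with the lowest mean, 5754 with a mean below 2.86, were left out, and 17263 were tested. Tests used limma 3.58.1 in R 4.3.3, with one mean per group fitted to all 24 samples and empirical Bayes moderation with a mean-variance trend. Adjusted p for a gene is the Benjamini-Hochberg value from limma over all tested genes, two-sided, with a threshold of 0.05. These p-values measure the spread between samples of a group. The median SE of a log2 fold change was 0.15, and 0.21 for the additivity test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

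Gene lists numbered 33, with 24 pathways and 9 cell types, and their membership was fixed before the data were examined. They were tested with camera of limma at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists of a comparison. Camera with an estimated correlation was far stricter. Counts adjusted over the list alone use the Benjamini-Hochberg value within the members of that list. Of the members, 5 had no row in the table (Ckmt1, Glp1r, Il6, Th and Dbh) and were not analysed here. Reads shared with related sequences make the values of glycolysis genes with pseudogenes, of Eno1 and of the alpha globin genes Hba-a1 and Hba-a2 uncertain.

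Genes named in the report followed a rule. Gipr and Ucp1 were always named. Each of 5 comparisons gave the 6 highest and 6 lowest log2 fold changes among genes that passed, had a mean of at least 5.33 and showed no overlap between the 6 and 6 samples; predicted models and immune receptor segments were passed over. Lists that passed camera or had 3 or more members called gave up to 3 members with the smallest p. LAGIPRA against PairFedVehicle gave the 3 highest and 3 lowest, and not every gene met by the rule is printed. The results of 3 genes are not reported here. With 6 and 6 samples, 0.216% of genes show no overlap by chance.

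Length slopes were taken by regressing the values of each library, relative to the mean of all libraries, on log2 transcript length from GENCODE mouse M21, known for 15407 of the tested genes (89.2%). Length slopes, the value of 1 read and skeletal muscle means were compared between groups with exact permutation tests over the 924 assignments, two-sided, and adjusted over 18 tests. Principal components of the tested genes explained 24.6%, 13.5% and 12.2% of the variance. No library was left out. The alternatives tried were other filters, thresholds, normalization and variance models, sample weights, covariates, removal of each library, other list tests and corrections for transcript length and depth.

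The procedure was tested on simulated data in which every gene kept its own mean and spread and 100 genes per effect size were changed. With an added log2 change of 1, it called 75% of the genes for TZP against Vehicle, 68% for LAGIPRA against Vehicle, 72% for PairFedVehicle against Vehicle, 72% for TZP against PairFedVehicle, 71% for TZP against LAGIPRA and 77% for LAGIPRA against PairFedVehicle. With 0.5 it called 37%, 42%, 29%, 33%, 40% and 46% in that order. False calls were 4.27%, 2.65%, 3.81%, 3.67%, 5.13% and 3.15% of those made, and the sign was right in all.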

Results

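PolyA RNA of brown adipose tissue from C57BL/6J mice was sequenced in 24 samples, 6 in each of 4 groups. The groups received vehicle (Vehicle), a long-acting agonist of the GIP receptor (LAGIPRA), tirzepatide, which activates the receptors for GIP and GLP-1 (TZP), or vehicle with pair feeding (PairFedVehicle). The description codes of the samples run consecutively within each group. Whether samples were processed in that order was not given, and an effect of such an order could not be told apart from treatment. Pair-fed animals are given only as much food as another group eats; which group set the amount was not given in the sources used here. The deposited table held 23017 genes, and 17263 were tested after the 25% with the lowest mean were left out. The scale was inferred from the values as log2 with an offset near 1, which would understate fold changes of weakly expressed genes. Some values lie slightly below 0, the lowest at -0.50. Libraries of the same group correlated across genes at r = 0.911 to 0.977, where genes are not independent replicates.

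Libraries differed in 3 measured properties. Read totals were not analysed here. The most frequent low value of a library, taken as that of 1 read, ran from 0.853 in Vehicle 1 to 2.19 in LAGIPRA 4. It would be larger in a shallower library. These libraries also had the fewest and most genes at the zero level, 860 and 1267. Depth and the mix of cells could each set that number, so the value of 1 read is no measure of depth alone. Group means of the value of 1 read were 1.07 (SD 0.255) in Vehicle, 1.57 (SD 0.449) in LAGIPRA, 1.51 (SD 0.373) in TZP and 1.23 (SD 0.156) in PairFedVehicle (n = 6 each). LAGIPRA and TZP each differed from Vehicle with an exact two-sided permutation p = 0.0411 (adjusted over 18 tests, 0.117). The slope of expression on transcript length was -0.0698 log2 per doubling (SD 0.0772) in TZP against 0.0466 (SD 0.0188) in Vehicle, 0.0102 (SD 0.0203) in LAGIPRA and 0.0129 (SD 0.0137) in PairFedVehicle; TZP minus Vehicle was -0.116 (exact permutation p = 0.00649, adjusted 0.0779). Within TZP the slope was -0.0691, -0.0938, -0.123 and -0.172 in libraries 3 to 6, against 0.0178 and 0.0211 in libraries 1 and 2. Skeletal muscle markers averaged 6.48 (SD 3.23) in Vehicle, 8.10 (SD 1.15) in LAGIPRA, 6.70 (SD 2.83) in TZP and 6.50 (SD 3.08) in PairFedVehicle, and were close to absent in Vehicle 1 (1.12), TZP 3 (1.26) and PairFedVehicle 5 (0.96).

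**Figure D1:**
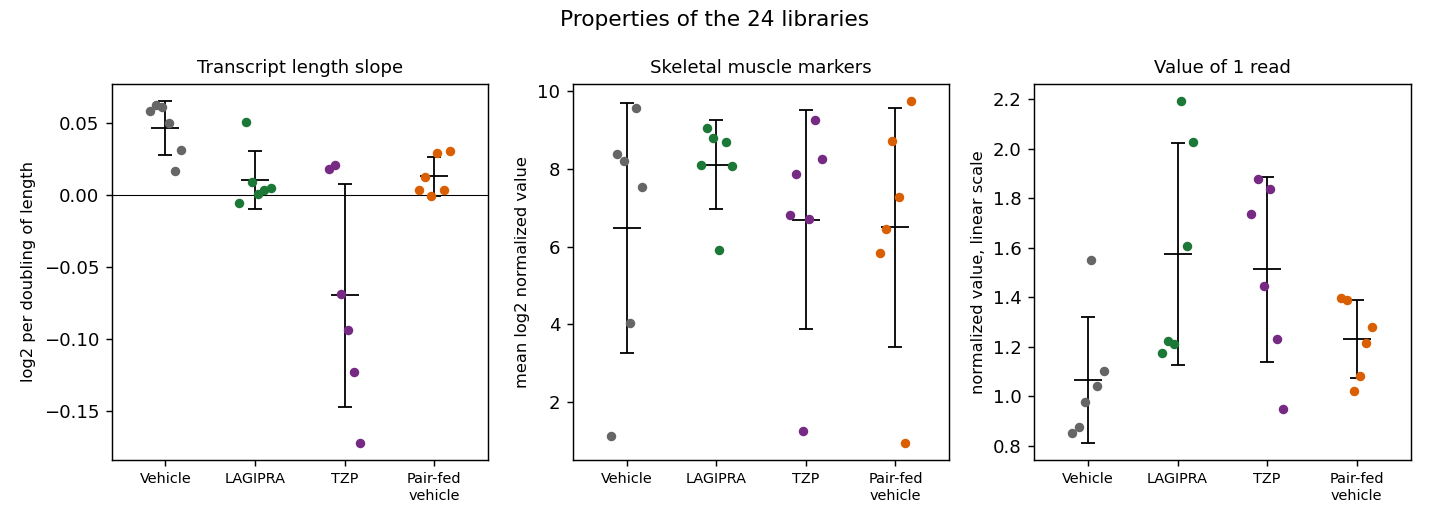
Slope of expression on transcript length (log2 per doubling), mean log2 value of skeletal muscle markers, and value of 1 read for each of the 24 libraries by group. Dash and bar give the mean and SD of the 6 samples.

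The comparison of TZP with Vehicle asked which brown fat genes differed under tirzepatide, with its effects on food intake and body weight included. Most measured genes of the mitochondrial respiratory chain rose, and some genes of matrix, immediate early response, interferon response and blood vessels fell. As lists, none of these passed with an estimated correlation (adjusted p = 0.588). Mcee (Entrez 73724), whose product handles methylmalonyl-CoA from valine and isoleucine, rose from 8.80 ± 0.14 to 9.42 ± 0.16 (SD, n = 6; log2 change 0.62, SE 0.089, adjusted p = 0.000428), without overlap of the 6 and 6 samples. Ucp1 (Entrez 22227), the uncoupling protein of brown fat mitochondria, rose from 14.90 ± 0.14 to 15.39 ± 0.30 (0.50, SE 0.119, adjusted p = 0.00579). Its change was 0.365 after correction for transcript length and no longer passed (adjusted p = 0.0606), but 0.757 (adjusted p = 0.0295) with the length slope as a covariate and 0.756 (adjusted p = 0.0126) with TZP libraries 1 and 2 alone. Ucp1 took equal values in several libraries, such as 15.392 in TZP 2 and PairFedVehicle 3, 4 and 6. Quantile normalization gives genes of equal rank the same value. The log2 changes of Ucp1 may thus be steps between ranks among the highest genes rather than measured folds. Cldn5 (Entrez 12741), a tight junction gene of endothelium, fell from 12.03 ± 0.26 to 11.01 ± 0.30 (-1.02, SE 0.129, adjusted p = 0.000201), with no overlap. In all 3805 genes passed, 2021 higher and 1784 lower, and 1476 of them changed at least 1.5-fold (439 higher, 1037 lower). With the value of 1 read as a covariate, more genes were lower than higher.

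Of 71 oxidative phosphorylation genes 45 rose and 0 fell (median 0.30; 56 higher when adjusted over the list alone; camera adjusted p = 2.82e-14; adjusted p = 0.588 with an estimated correlation). Among the complex I subunits Ndufb5 (Entrez 66046) rose by 0.53 (SE 0.097, adjusted p = 0.00126) and Ndufa8 by 0.41 (SE 0.088, adjusted p = 0.00322), the latter without overlap. Branched-chain amino acid breakdown had 7 genes higher and 0 lower of 24 (median 0.23; 10 higher when adjusted over the list alone; camera adjusted p = 0.000138, and 0.692 with an estimated correlation). The call ended with the one-read level covariate (0.0525, adjusted p = 0.244). This count is not independent evidence of direction, because the theme was known from the study's publication. Besides Mcee, the group held Bcat2, which starts the pathway (0.30, SE 0.073, adjusted p = 0.00683). The list mean lay above all Vehicle samples (-0.312 to -0.0251) only in TZP 1, 2 and 4 (0.187, 0.228 and 0.230). In TZP 3, 5 and 6 (-0.1045, -0.0798 and -0.286) it lay within their range. Prodh (Entrez 19125), the first enzyme of proline breakdown, rose by 1.19 (SE 0.182, adjusted p = 0.000539). The list of other amino acid breakdown, with 5 higher and 1 lower of 14, did not pass (median 0.28, camera adjusted p = 0.141). Pyruvate dehydrogenase and citrate cycle genes had 5 higher and 0 lower of 22 (median 0.22, camera adjusted p = 0.0012, and 0.692 with an estimated correlation), with Pdhb at 0.46 (SE 0.14, adjusted p = 0.0214). Fatty acid oxidation had 4 higher and 1 lower of 20 (median 0.18, camera adjusted p = 0.0116, and 0.725 with an estimated correlation). Eci1 rose by 0.41 (SE 0.11), but Cpt1a, which admits long-chain fatty acids to mitochondria, fell (-0.57, SE 0.147, adjusted p = 0.0087). The citrate cycle and fatty acid oxidation list means also lay above all Vehicle samples only in TZP 1, 2 and 4. The thermogenic list had 5 higher and 2 lower of 20 (median 0.36; 10 and 2 when adjusted over the list alone; camera adjusted p = 0.035, and 0.692 with an estimated correlation), with the nuclear receptor gene Esrra at 0.39 (SE 0.087, adjusted p = 0.0042). The list mean lay above all Vehicle samples (-0.456 to 0.195) only in TZP libraries 1 (0.571) and 2 (0.430), and within their range in TZP libraries 3 to 6 (-0.420 to -0.0905).

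**Figure D2:**
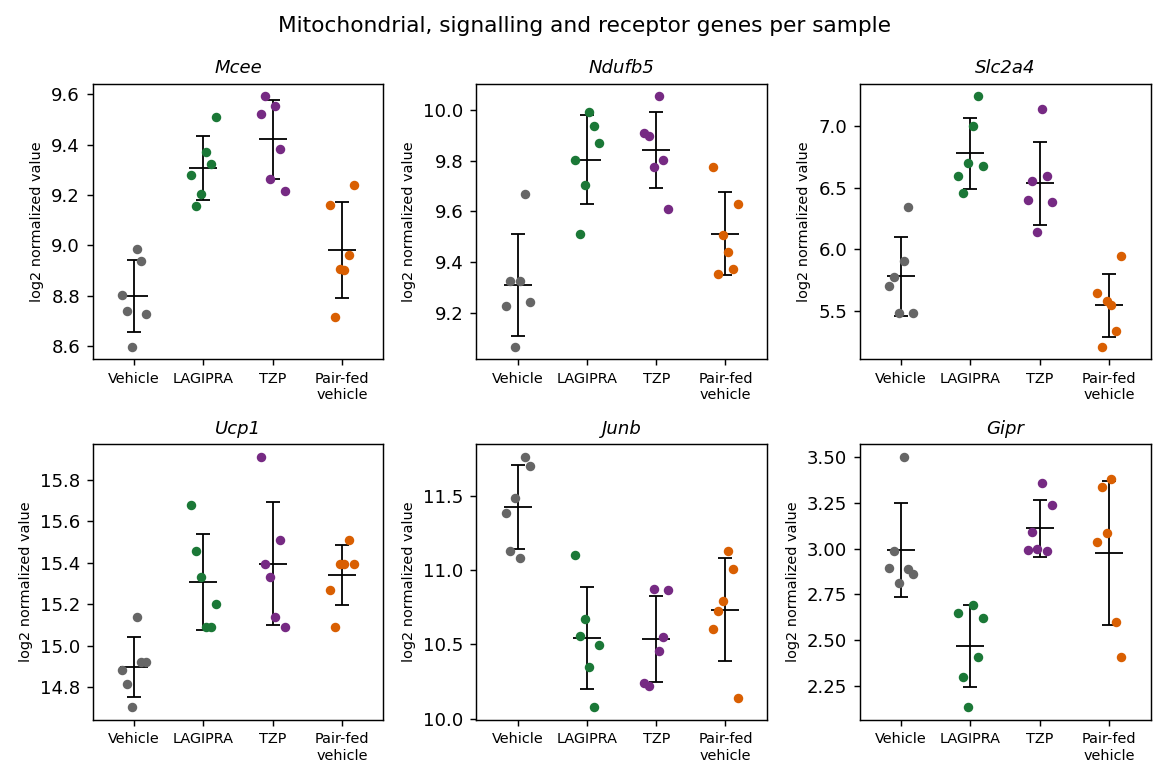
Normalized log2 value per sample of Mcee, Ndufb5, Slc2a4, Ucp1, Junb and Gipr in the 4 groups. Dash and bar give the mean and SD of 6 samples.

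Glucose and lipid genes moved in part. Slc2a4 (Entrez 20528), the insulin-responsive glucose transporter, rose from 5.78 ± 0.32 to 6.53 ± 0.34 (0.75, SE 0.167, adjusted p = 0.00382), and Pfkfb1 rose by 0.57 (SE 0.13, adjusted p = 0.00466). Glycolysis had 3 higher and 0 lower of 20 (median 0.18, camera adjusted p = 0.035, and 0.692 with an estimated correlation). Insulin signalling had 0 higher and 10 lower of 18 (median -0.40; 12 lower when adjusted over the list alone; camera adjusted p = 0.000277, and 0.588 with an estimated correlation). The genes that fell did not point one way: Pik3r1 (-0.62, SE 0.155) carries the insulin signal, whereas Grb10 (-0.97, SE 0.21) and Gsk3b (-0.50, SE 0.115) restrain it. The list's median turned to 0.0112 with TZP libraries 1 and 2 alone and to 0.221 with the length slope as a covariate. Lipogenesis did not pass (2 higher and 2 lower of 18; median 0.05, mean -0.09, camera adjusted p = 0.85; -0.1261 with the one-read level covariate, adjusted p = 0.0326): Mlxipl, a carbohydrate-sensing regulator, rose by 0.60 (SE 0.148), and Scd1 (Entrez 20249), a desaturase, fell from 15.08 ± 0.31 to 13.77 ± 0.65 (-1.31, SE 0.232, adjusted p = 0.00105). The lipogenesis mean lay above all Vehicle samples (0.0141 to 0.404) in TZP 1, 2 and 4 (0.431, 0.517 and 0.679). In TZP 3, 5 and 6 (-0.446, -0.0933 and -0.234) it lay below all of them. Triglyceride synthesis had 6 higher and 2 lower of 16 (median 0.19, camera adjusted p = 0.152), among them Agpat2 at 0.51 (SE 0.123) and Dgat1 at 0.37 (SE 0.093). Lipid uptake (2 higher, 0 lower of 13, camera adjusted p = 0.763), lipolysis (1 and 1 of 10, 0.152) and cholesterol synthesis (0 and 1 of 22, 0.637) did not pass.

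Matrix genes fell in 10 of 23, with 0 higher (median -0.50; 12 lower when adjusted over the list alone; camera adjusted p = 6.81e-07, and 0.588 with an estimated correlation). Sparc fell from 11.50 ± 0.06 to 11.11 ± 0.13 (-0.40, SE 0.062, adjusted p = 0.000599), the crosslinking enzyme gene Lox by -0.77 (SE 0.13, adjusted p = 0.000854) and Fn1 by -1.18 (SE 0.211, adjusted p = 0.00108), each without overlap. Immediate early genes fell in 7 of 12, with 0 higher (median -0.54, camera adjusted p = 2.55e-05, and 0.588 with an estimated correlation). They included Egr1 (Entrez 13653; -1.88, SE 0.323, adjusted p = 0.000914) and Junb (Entrez 16477; 10.54 ± 0.29 against 11.43 ± 0.28, -0.89, SE 0.173, adjusted p = 0.00169), without overlap, and Zfp36 (-0.70, SE 0.146, adjusted p = 0.00252). Interferon response had 4 lower of 17 (8 when adjusted over the list alone; median -0.59, camera adjusted p = 2.81e-05, and 0.588 with an estimated correlation), with Ifit1 at -0.73 (SE 0.232, adjusted p = 0.0279). Cytokines and chemokines had 3 lower of 14 (median -0.68, camera adjusted p = 0.0012, and 0.588 with an estimated correlation), Cxcl1 among them (-1.62, SE 0.345, adjusted p = 0.00293). The unfolded protein response had 8 lower of 16 (median -0.30, camera adjusted p = 1.16e-04, and 0.588 with an estimated correlation), led by Sel1l (-0.82, SE 0.149, adjusted p = 0.00125).

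Markers of other cells moved with these groups. Endothelial markers had 6 lower of 11 (median -0.21, camera adjusted p = 0.0012, and 0.588 with an estimated correlation), and Pdgfrb of pericytes fell (-0.72, SE 0.112, adjusted p = 0.000578). The endothelial fall rested on TZP libraries 3 to 6, which have the low length slope: with libraries 1 and 2 alone the list median was -0.0182 (adjusted p = 0.106). All 5 erythroid markers fell (median -1.08, camera adjusted p = 0.00291, and 0.588 with an estimated correlation), Hbb-bt by -1.30 (SE 0.377, adjusted p = 0.0174). The erythroid mean was low in TZP libraries 1, 2, 4 and 5 (-1.56 to -1.16), and in TZP 3 (-0.0167) and TZP 6 (0.033) it lay within the range of Vehicle (-0.255 to 1.15). Macrophage markers had 1 lower of 16, Mrc1 (-1.08, SE 0.24, adjusted p = 0.00396), with a median of -0.48 (camera adjusted p = 0.0012, and 0.692 with an estimated correlation). Cell cycle genes had 0 single calls of 18 but a list median of -0.38 (camera adjusted p = 0.0397, and 0.803 with an estimated correlation), which turned to 0.0852 with the one-read level covariate. The cell cycle mean was below 0 in TZP 1, 2 and 4 (-0.740, -0.443 and -0.417) and not in TZP 3, 5 and 6 (0.731, 0.531 and 0.738), all 6 within the range of Vehicle (-0.751 to 1.22). The lists of creatine and calcium cycling (0 called of 10), ATF4 response (0 higher, 3 lower of 20), glucocorticoid response (2 and 1 of 11), clock (2 and 1 of 17), cAMP signalling (0 and 1 of 14), white adipocyte (0 and 1 of 9), skeletal muscle (0 of 16), lymphocyte (0 of 4), smooth muscle (1 and 3 of 8), fibroblast (0 and 2 of 7) and Schwann cell markers (0 of 7) did not pass.

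Genes that fell in TZP had long transcripts, with a median of 5544.5 bases against 1860.0 for those that rose. After a correction for transcript length 2592 genes passed, 1191 higher and 1401 lower, and with the length slope as a covariate 203 did. Among the 75 named genes called, 7 were called under every setting tried: Mcee, Prodh, Junb, Zfp36, Cxcl1, Sparc and Cldn5. The largest decrease with no overlap among genes of at least median expression, Thbs1 (Entrez 21825; 4.87 ± 1.02 against 7.27 ± 0.35, -2.40, SE 0.324, adjusted p = 0.000281), and the receptor gene Cd93 (-2.08, SE 0.303, adjusted p = 0.000431) were not among them. Among genes of at least median expression the largest increases with no overlap were Nrtn (0.87, SE 0.185, adjusted p = 0.00288) and Mpzl2 (0.87, SE 0.176, adjusted p = 0.00212). Gipr (Entrez 381853), the receptor gene, did not differ (3.11 ± 0.16 against 2.99 ± 0.26, 0.12, adjusted p = 0.687). Across all genes 940 showed no overlap of the 6 and 6 samples, 5.45% against 0.216% by chance.

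The comparison of LAGIPRA with Vehicle asked what agonism at the GIP receptor alone did. Many mitochondrial and fuel-oxidizing genes rose, and some genes of chemokines, interferon response and matrix fell. As lists, none of these passed with an estimated correlation (adjusted p = 0.353 to 0.361). Slc2a4 rose from 5.78 ± 0.32 to 6.78 ± 0.29 (0.996, SE 0.167, adjusted p = 0.00376), without overlap. Ndufv2, a complex I subunit, rose from 10.63 ± 0.15 to 11.12 ± 0.15 (0.49, SE 0.091, adjusted p = 0.00514), and Mcee from 8.80 ± 0.14 to 9.31 ± 0.13 (0.51, SE 0.089, adjusted p = 0.00455), each without overlap. Ccl2 (Entrez 20296), a chemokine that draws monocytes, fell from 9.02 ± 0.50 to 7.42 ± 0.60 (-1.60, SE 0.443, adjusted p = 0.0224), and the heme oxygenase gene Hmox1 (Entrez 15368) by -1.57 (SE 0.341, adjusted p = 0.00891), each without overlap. In all 2370 genes passed, 1502 higher and 868 lower. After the correction for transcript length the division was 1084 higher and 1168 lower of 2252.

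Oxidative phosphorylation had 54 higher and 0 lower of 71, and 66 higher when adjusted over the list alone. The median was 0.36 (camera adjusted p = 1.71e-23, and 0.353 with an estimated correlation). The list mean lay above all Vehicle samples (-0.398 to 0.0714) in LAGIPRA 1, 4, 5 and 6. In LAGIPRA 2 and 3 (-0.0276 and 0.0361) it lay within their range. Pyruvate dehydrogenase and citrate cycle genes had 17 higher of 22 (median 0.38; 21 when adjusted over the list alone; camera adjusted p = 2.28e-10, and 0.353 with an estimated correlation): Pdhx rose by 0.51 (SE 0.104, adjusted p = 0.00682), Sdhd by 0.43 (SE 0.088, adjusted p = 0.00726) and Dlst by 0.45 (SE 0.106, adjusted p = 0.0123). Branched-chain amino acid breakdown had 16 higher and 0 lower of 24 (median 0.34; 22 when adjusted over the list alone; camera adjusted p = 2.37e-10, and 0.353 with an estimated correlation), again not independent evidence of direction, and Acad8 of the valine pathway rose by 0.47 (SE 0.095, adjusted p = 0.00682). Other amino acid breakdown had 8 higher of 14 (median 0.36, camera adjusted p = 0.00299, and 0.353 with an estimated correlation), with Prodh at 0.98 (SE 0.182, adjusted p = 0.00514). Fatty acid oxidation had 14 higher and 1 lower of 20 (median 0.34, camera adjusted p = 5.61e-07, and 0.361 with an estimated correlation). Acadl rose by 0.37 (SE 0.094) and Etfb by 0.46 (SE 0.111). The thermogenic list had 7 higher and 0 lower of 20 (median 0.31, camera adjusted p = 0.000287, and 0.361 with an estimated correlation). Ucp1 rose by 0.41 (SE 0.119, adjusted p = 0.0274), a call that ended after the length correction (0.339, adjusted p = 0.0816), with muscle and lymphocyte covariates (0.423, adjusted p = 0.0569), with the one-read level covariate (0.434, adjusted p = 0.134), with no filter (adjusted p = 0.0526) and without the 3 libraries lowest in muscle (adjusted p = 0.0608).

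Some fat-making genes rose as well. Thrsp, a lipogenic regulator, rose from 13.50 ± 0.23 to 14.36 ± 0.36 (0.86, SE 0.214, adjusted p = 0.0148), Mlxipl by 0.77 (SE 0.148, adjusted p = 0.00526) and Srebf1 by 0.42 (SE 0.088, adjusted p = 0.00787). Lipogenesis had 4 higher and 0 lower of 18 (median 0.25, camera adjusted p = 0.00984, and 0.537 with an estimated correlation), a median that turned to -0.075 with the one-read level covariate (adjusted p = 0.86). Triglyceride synthesis had 3 higher of 16 (7 when adjusted over the list alone; median 0.28, camera adjusted p = 0.0116, and 0.492 with an estimated correlation), with Dgat2 at 0.53 (SE 0.134, adjusted p = 0.0158). Lipolysis had 3 higher of 10 (median 0.19, camera adjusted p = 0.00357, and 0.367 with an estimated correlation), but the members were opposed in function: Pnpla2 encodes the lipase (0.44, SE 0.117, adjusted p = 0.02) and G0s2 its inhibitor (0.76, SE 0.16, adjusted p = 0.00758). Glycolysis had 4 higher and 1 lower of 20 (median 0.24, camera adjusted p = 0.00214, and 0.388 with an estimated correlation). Insulin signalling did not pass (2 higher, 2 lower of 18; camera adjusted p = 0.344).

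Interferon response had 10 lower of 17 (median -0.82; 13 when adjusted over the list alone; camera adjusted p = 1.04e-09, and 0.353 with an estimated correlation). Ifit1 fell from 7.22 ± 0.41 to 5.95 ± 0.26 (-1.27, SE 0.232, adjusted p = 0.00514) and Irf7 by -1.16 (SE 0.255, adjusted p = 0.00934). Cytokines and chemokines had 8 lower of 14 (median -1.19, camera adjusted p = 4.34e-07, and 0.353 with an estimated correlation), immediate early genes 5 of 12 (median -0.66, camera adjusted p = 2.55e-05, and 0.353 with an estimated correlation) and matrix genes 7 of 23 (median -0.63, camera adjusted p = 1.19e-08, and 0.353 with an estimated correlation), Timp1 and Lox among them (-1.46, SE 0.341; -0.73, SE 0.13). The unfolded protein response had 9 lower of 16 (median -0.34, camera adjusted p = 5.08e-07, and 0.353 with an estimated correlation), with Sdf2l1 at -0.85 (SE 0.224). The ATF4 list had 2 higher and 4 lower of 20 (median -0.12, camera adjusted p = 0.044, and 0.361 with an estimated correlation), with the serine synthesis gene Psat1 at -0.72 (SE 0.13, adjusted p = 0.00514). Macrophage markers had 6 lower of 16 (median -0.83, camera adjusted p = 6.8e-07, and 0.361 with an estimated correlation), C1qa by -0.84 (SE 0.206, adjusted p = 0.0141). The macrophage mean was low in LAGIPRA 4 to 6 (-0.864, -0.842 and -0.653). In LAGIPRA 1 to 3 (0.0996, 0.1225 and -0.0191) it lay within the range of Vehicle (-0.345 to 0.718). The matrix mean divided alike, at -0.510, -0.436 and -0.4225 against 0.0876, 0.1445 and 0.0397 (Vehicle -0.248 to 0.637). LAGIPRA 4 to 6 also had the higher values of 1 read (2.19, 1.61 and 2.03, against 1.18, 1.22 and 1.21). Cell cycle genes had 4 lower of 18 (median -0.88, camera adjusted p = 4.34e-07, and 0.361 with an estimated correlation), Mki67 by -1.31 (SE 0.322, adjusted p = 0.0143), and fibroblast markers 1 of 7 (median -0.32, camera adjusted p = 0.0122, and 0.361 with an estimated correlation).

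Gipr was 2.47 ± 0.22 in LAGIPRA against 2.99 ± 0.26 in Vehicle (-0.53, SE 0.189, adjusted p = 0.0637), without overlap but not past the threshold. The LAGIPRA count changed with single libraries and with a covariate that itself differs between the groups. With the value of 1 read as that covariate 45 genes passed, and of the 74 named genes called only Lmf1 and Poln were called under every setting. The count was 1207 without Vehicle 1, 1039 without Vehicle 3, 3819 without Vehicle 5, 1166 without Vehicle 6, 971 without LAGIPRA 4, 945 without LAGIPRA 5 and 1391 without LAGIPRA 6. It was 1043 with muscle and lymphocyte covariates and 1233 without the 3 libraries lowest in muscle, and array weights raised it. Of all genes 802 showed no overlap, 4.65% against 0.216% by chance.

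The comparison of PairFedVehicle with Vehicle asked what restricted feeding did without drug. Fat and cholesterol synthesis fell sharply. Fasn (Entrez 14104), the fatty acid synthase, fell from 12.59 ± 0.33 to 9.76 ± 0.37 (-2.83, SE 0.368, adjusted p = 2.9e-05), and Acly (Entrez 104112), which supplies its acetyl-CoA, from 9.64 ± 0.28 to 7.14 ± 0.10 (-2.49, SE 0.281, adjusted p = 5.65e-06). Fdps (Entrez 110196) of the cholesterol pathway fell from 6.30 ± 0.09 to 5.21 ± 0.18 (-1.09, SE 0.091, adjusted p = 1.44e-07). The natriuretic peptide clearance receptor gene Npr3 (Entrez 18162) fell from 7.47 ± 0.26 to 5.58 ± 0.30 (-1.89, SE 0.147, adjusted p = 4.9e-08) and leptin, Lep (Entrez 16846), from 8.65 ± 0.33 to 7.06 ± 0.46 (-1.59, SE 0.209, adjusted p = 3.13e-05). Each was free of overlap. In all 1487 genes passed, 856 higher and 631 lower. After the correction for transcript length 634 were higher and 687 lower of 1321.

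Lipogenesis had 14 lower and 1 higher of 18 (median -1.24, camera adjusted p = 9.35e-16, and 0.185 with an estimated correlation), with Acaca (Entrez 107476) at -2.35 (SE 0.305, adjusted p = 2.84e-05). Cholesterol synthesis had 15 lower and 0 higher of 22 (median -0.65; 18 when adjusted over the list alone; camera adjusted p = 8.68e-19, and 0.00423 with an estimated correlation), with Idi1 at -0.87 (SE 0.098, adjusted p = 5.65e-06) and Nsdhl at -0.95 (SE 0.108, adjusted p = 6.92e-06). Glycolysis had 10 lower and 1 higher of 20 (median -0.33, camera adjusted p = 1e-06, and 0.396 with an estimated correlation): Pkm fell (-0.66, SE 0.085), as did Eno1 (-0.84, SE 0.14) and Ldha (-0.54, SE 0.096). Lipolysis had 4 higher of 10 (median 0.28, camera adjusted p = 9.34e-05, and 0.396 with an estimated correlation), Pnpla2 by 0.56 (SE 0.117) and its inhibitor G0s2 by 1.05 (SE 0.16, adjusted p = 0.000174). Lipid uptake had 5 higher and 1 lower of 13 (median 0.21, camera adjusted p = 0.0144, and 0.396 with an estimated correlation), with the fatty acid transporter gene Slc27a1 at 0.73 (SE 0.109, adjusted p = 0.000149). White adipocyte markers had 3 lower of 9 (median -0.27, camera adjusted p = 0.000427, and 0.396 with an estimated correlation). Insulin signalling had 3 lower of 18 (median -0.19, camera adjusted p = 0.00803, and 0.513 with an estimated correlation; 0.023 with the length slope covariate and 0.0243 with muscle added), among them Pik3r1 (-1.08, SE 0.155) and the inhibitory adaptor gene Grb14 (Entrez 50915; -0.87, SE 0.109, adjusted p = 1.86e-05).

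**Figure D3:**
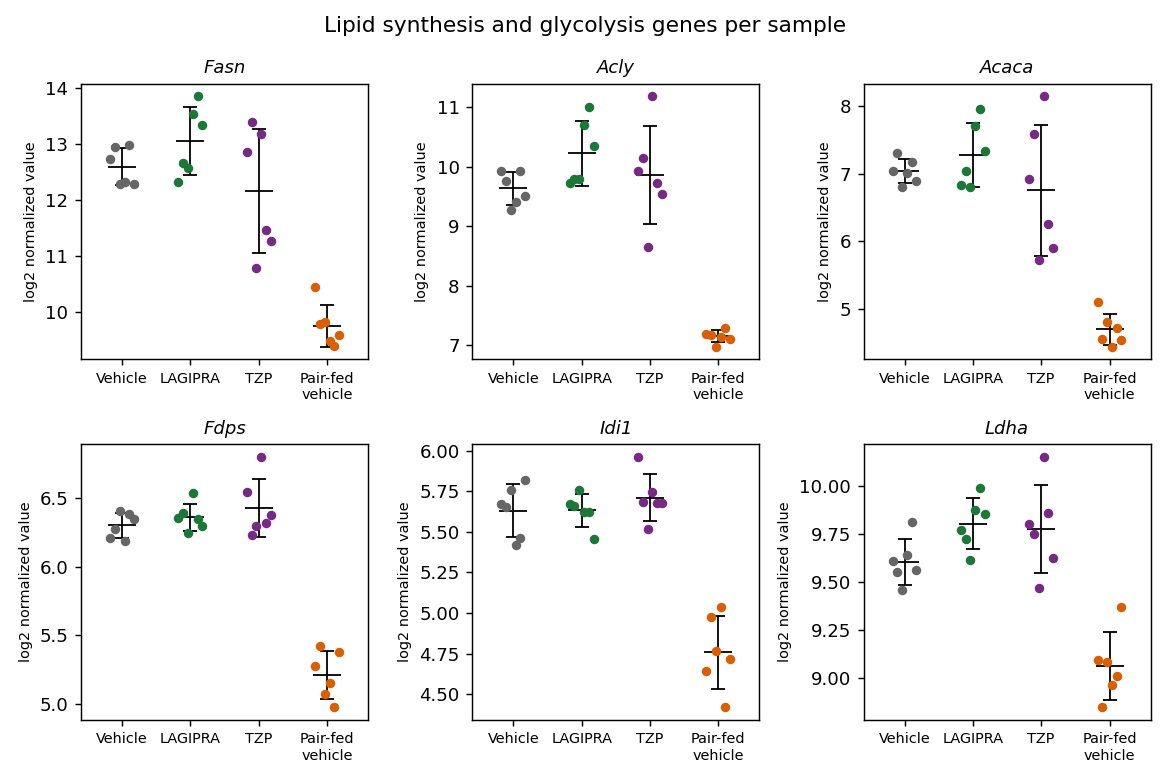
Normalized log2 value per sample of Fasn, Acly, Acaca, Fdps, Idi1 and Ldha in the 4 groups. Dash and bar give the mean and SD of 6 samples.

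Few mitochondrial genes passed. Oxidative phosphorylation had 4 higher of 71 (median 0.15, camera adjusted p = 2.83e-05, and 0.709 with an estimated correlation), with Cox8a at 0.64 (SE 0.084, adjusted p = 3.25e-05). Fatty acid oxidation had 2 higher and 1 lower of 20 (median 0.20, camera adjusted p = 0.00203, and 0.709 with an estimated correlation). For branched-chain amino acid breakdown 5 genes were higher and 0 lower of 24 (median 0.13, camera adjusted p = 0.00162, and 0.709 with an estimated correlation), not independent evidence of direction. Hsd17b10 of the isoleucine pathway rose by 0.71 (SE 0.105, adjusted p = 0.000125) and Pccb by 0.36 (SE 0.091, adjusted p = 0.0148). Pyruvate dehydrogenase and citrate cycle genes had 0 calls of 22 (limma; camera adjusted p = 0.994). The thermogenic list, 4 higher of 20, did not pass (median 0.11, camera adjusted p = 0.151), although Ucp1 rose by 0.45 (SE 0.119, adjusted p = 0.0208; 0.393 and 0.0661 after the length correction) and Zic1 by 0.87 (SE 0.164, adjusted p = 0.00174). Matrix genes had 4 lower of 23 (median -0.44, camera adjusted p = 5.18e-06, and 0.483 with an estimated correlation), Sparc by -0.53 (SE 0.062, adjusted p = 9.13e-06). Immediate early genes had 3 lower of 12 (median -0.36, camera adjusted p = 0.000182, and 0.396 with an estimated correlation), Fosb by -3.25 (SE 0.509, adjusted p = 0.000246), and cytokines and chemokines 3 of 14 (median -0.61, camera adjusted p = 0.000427, and 0.398 with an estimated correlation). The unfolded protein response (1 lower of 16, camera adjusted p = 0.0017, estimated 0.513), the ATF4 list (1 higher and 1 lower of 20, 0.0464, estimated 0.483), fibroblast (1 lower of 7, 0.00571, estimated 0.467), macrophage (0 of 16, 0.0138, estimated 0.709) and cell cycle genes (0 of 18, 0.00205, estimated 0.709) had lower medians.

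The strongest increases under pair feeding among genes of at least median expression were those of Cfd (Entrez 11537), the adipocyte factor adipsin (9.30 ± 0.34 to 10.95 ± 0.73; 1.65, SE 0.269, adjusted p = 0.000406), and the glutathione transferase gene Gstt2 (Entrez 14872; 5.89 ± 0.12 to 7.33 ± 0.20, 1.45, SE 0.095, adjusted p = 2.84e-09), each without overlap. Gipr did not differ (adjusted p = 0.977). Of the 64 named genes called, 50 were called under every setting tried. No-overlap genes numbered 821, which is 4.76% against 0.216% by chance.

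The comparison of TZP with PairFedVehicle asked which differences remained beside a group whose food was restricted. Genes of fat synthesis, cholesterol synthesis and glycolysis were higher in TZP. Acly was 9.86 ± 0.83 against 7.14 ± 0.10 (2.72, SE 0.281, adjusted p = 1.69e-06), Fasn 12.16 ± 1.11 against 9.76 ± 0.37 (2.39, SE 0.368, adjusted p = 0.000183) and Npr3 7.27 ± 0.30 against 5.58 ± 0.30 (1.68, SE 0.147, adjusted p = 3.16e-07). Fdps was 6.43 ± 0.21 against 5.21 ± 0.18 (1.22, SE 0.091, adjusted p = 2.46e-08). The means of TZP and Vehicle were closer to each other in these genes than either was to PairFedVehicle. For lipogenesis the TZP mean joins libraries above all Vehicle samples (TZP 1, 2 and 4) and below all of them (TZP 3, 5 and 6). In all 2832 genes passed, 1448 higher and 1384 lower, with median transcript lengths of 1939 and 4977. With the length slope as a covariate 970 passed.

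Lipogenesis had 14 higher and 1 lower of 18 (median 1.004, camera adjusted p = 5.56e-11, and 0.255 with an estimated correlation), cholesterol synthesis 15 higher of 22 (median 0.63, camera adjusted p = 5.56e-11, and 0.0599 with an estimated correlation) and glycolysis 14 higher and 1 lower of 20 (median 0.51, camera adjusted p = 2.7e-10, and 0.228 with an estimated correlation). Nsdhl was higher by 1.13 (SE 0.108, adjusted p = 8.9e-07), Idi1 by 0.95 (SE 0.098, adjusted p = 1.69e-06), Pkm by 0.76 (SE 0.085, adjusted p = 4.99e-06) and Ldha by 0.71 (SE 0.096, adjusted p = 4.13e-05). Pyruvate dehydrogenase and citrate cycle genes had 6 higher and 0 lower of 22 (median 0.12, camera adjusted p = 0.00134, and 0.938 with an estimated correlation), Pdhb by 0.87 (SE 0.14, adjusted p = 0.000294). Oxidative phosphorylation had 8 higher and 1 lower of 71 (median 0.16, camera adjusted p = 9.98e-06, and 0.938 with an estimated correlation). Cox8a was the lower one (-0.46, SE 0.084, adjusted p = 0.000972). The branched-chain amino acid list had 3 higher and 1 lower of 24 and did not pass (median 0.09, camera adjusted p = 0.307), which is not independent evidence of direction. It passed with TZP libraries 1 and 2 alone (0.256, adjusted p = 0.000119), the length slope covariate (0.196, 0.00413) and length slope with muscle (0.197, 0.00483). The median turned to -0.0126 with the one-read level covariate. Mcee was higher by 0.44 (SE 0.089, adjusted p = 0.00214) and Hsd17b10 lower (-0.40, adjusted p = 0.0115). Ucp1 did not differ (15.39 ± 0.30 against 15.34 ± 0.14, 0.054, SE 0.119, adjusted p = 0.815), the thermogenic list did not pass (4 higher, 1 lower of 20; camera adjusted p = 0.491), and Bmp8b was higher by 1.87 (SE 0.439, adjusted p = 0.00594).

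Endothelial markers were lower in 7 of 11 (median -0.29, camera adjusted p = 8.62e-06, and 0.228 with an estimated correlation), with Tek at -0.70 (SE 0.093, adjusted p = 3.55e-05) and Cdh5 at -0.50 (SE 0.078, adjusted p = 0.000189), without overlap. The list mean was -0.578 to -0.211 in TZP libraries 3 to 6, against -0.0326 and -0.0346 in TZP 1 and 2, with which alone the list passed as well. Interferon response had 2 lower of 17 (median -0.41, camera adjusted p = 0.00134, and 0.938 with an estimated correlation), Rsad2 by -1.14 (SE 0.201, adjusted p = 0.00068). Erythroid markers had 0 calls of 5 by limma and 4 lower when adjusted over the list alone (median -0.82, camera adjusted p = 0.0359, and 0.938 with an estimated correlation). Of the insulin receptor substrates, Irs1 (Entrez 16367) was lower (-1.01, SE 0.213, adjusted p = 0.00283), and so was Irs2 (-0.84, SE 0.251, adjusted p = 0.024). Grb14, an inhibitor of the receptor, was higher by 1.09 (SE 0.109, adjusted p = 1.62e-06). The insulin signalling list did not pass (2 higher, 2 lower of 18; median -0.21, camera adjusted p = 0.181). Lipid uptake (2 higher, 5 lower of 13; camera adjusted p = 0.149) and lipolysis (0 and 3 of 10; 0.0748) did not pass, though Slc27a1 was lower (-0.66, SE 0.109, adjusted p = 0.000406), as was G0s2 (-0.79, SE 0.16, adjusted p = 0.00214). The largest decrease with no overlap among well expressed genes was in Peg3os (Entrez 100169889), a noncoding transcript (7.31 ± 0.75 against 9.57 ± 0.39; -2.26, SE 0.26, adjusted p = 6.24e-06). Of 56 named genes called, 31 were called under every setting, and 850 genes showed no overlap (4.92% against 0.216% by chance).

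The direct comparison of TZP with LAGIPRA asked whether the dual agonist differed from GIP receptor agonism. Few genes did: 69 passed, 9 higher and 60 lower. Red cell genes were lower in TZP. Alas2 (Entrez 11656), the erythroid enzyme that starts heme synthesis, was 5.14 ± 0.79 against 7.03 ± 0.33 (-1.89, SE 0.416, adjusted p = 0.0468), and Hbb-bt 11.02 ± 0.78 against 12.83 ± 0.34 (-1.82, SE 0.377, adjusted p = 0.0468), each without overlap. Irs1 was lower (6.05 ± 0.33 against 7.02 ± 0.48, -0.97, SE 0.213, adjusted p = 0.0468), and the glucocorticoid-induced Fkbp5 (Entrez 14229) was higher (5.09 ± 0.40 against 4.06 ± 0.32, 1.03, SE 0.218, adjusted p = 0.0468). Gipr was 3.11 ± 0.16 against 2.47 ± 0.22, without overlap, and did not pass (0.65, SE 0.189, adjusted p = 0.0846).

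Erythroid markers had 3 lower of 5 (5 when adjusted over the list alone; median -1.56, camera adjusted p = 3.82e-07, and 0.225 with an estimated correlation). Endothelial markers had 1 lower of 11 (7 when adjusted over the list alone; median -0.23, camera adjusted p = 7e-06, and 0.225 with an estimated correlation) and smooth muscle 1 of 8 (median -0.34, camera adjusted p = 0.00505, and 0.225 with an estimated correlation), with Tek at -0.42 (SE 0.093, adjusted p = 0.0474). The endothelial list mean was again lowest in TZP libraries 3 to 6 (-0.578 to -0.211, against -0.0326 and -0.0346 in TZP 1 and 2 and -0.005 to 0.107 in LAGIPRA), though the list passed with TZP 1 and 2 alone. Insulin signalling had 1 lower of 18 (7 when adjusted over the list alone; median -0.34, camera adjusted p = 7.51e-05, and 0.466 with an estimated correlation). Lipogenesis had 0 single calls of 18 by limma and 4 lower when adjusted over the list alone (median -0.33, camera adjusted p = 7.51e-05, and 0.739 with an estimated correlation), and glucocorticoid response 1 higher of 11 (median 0.27, camera adjusted p = 0.0263, and 0.739 with an estimated correlation). The lipogenesis mean lay below all LAGIPRA samples (0.168 to 0.858) in TZP 3, 5 and 6, and within their range in TZP 1, 2 and 4. The medians of 7 further lists shifted with 0 single calls by limma. These were pyruvate dehydrogenase and citrate cycle (-0.15, camera adjusted p = 0.000177, estimated 0.794), fatty acid oxidation (-0.14, 0.00646, estimated 0.807), branched-chain amino acids (-0.12, 0.0125, estimated 0.849, not independent evidence of direction) and oxidative phosphorylation (-0.07, 0.0391, estimated 0.849). The others were cAMP signalling (-0.23, 0.0387, estimated 0.739), skeletal muscle (-1.40, 0.0476, estimated 0.849) and cell cycle (0.55, 0.000668, estimated 0.794). With TZP libraries 1 and 2 alone most of these medians turned: to 0.009 for pyruvate dehydrogenase and citrate cycle, 0.0818 for fatty acid oxidation, 0.0487 for branched-chain amino acids, 0.0113 for oxidative phosphorylation, 0.0046 for cAMP signalling and -0.1185 for cell cycle. Insulin signalling turned to 0.0157 in the same setting.

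The 60 genes lower in TZP and 9 higher had median transcript lengths of 5682 and 2042.5, and 0 passed with the length slope as a covariate. Single libraries decided the count: 1043 without TZP 1, 1088 without TZP 2, 6 without TZP 4, 1 without TZP 5 and 0 without TZP 6, and 23, 6, 0, 0, 1 and 0 without LAGIPRA 1 to 6. At unadjusted p < 0.05 there were 2835 genes, and 140 showed no overlap (0.811% against 0.216% by chance).

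LAGIPRA and PairFedVehicle were compared to ask whether GIP receptor agonism resembled restricted feeding. Fat synthesis was much higher in LAGIPRA: Fasn was 13.04 ± 0.61 against 9.76 ± 0.37 (3.28, SE 0.368, adjusted p = 4.5e-06), Acly 10.23 ± 0.54 against 7.14 ± 0.10 (3.09, SE 0.281, adjusted p = 2.57e-07) and Acaca differed by 2.59 (SE 0.305, adjusted p = 7.23e-06). Lower were Peg3os (-1.67, SE 0.26, adjusted p = 0.000178), the neutrophil gene S100a9 (-1.45, SE 0.205, adjusted p = 6.7e-05) and Ehhadh of peroxisomal oxidation (-1.41, SE 0.217, adjusted p = 0.000161). All 6 were called under every setting. In all 2046 genes passed, 1260 higher and 786 lower, and 1011 showed no overlap (5.86% against 0.216% by chance).

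Lipogenesis had 15 higher of 18 (median 1.40, camera adjusted p = 4.93e-21, and 0.0645 with an estimated correlation), cholesterol synthesis 15 of 22 (median 0.64, camera adjusted p = 2.99e-14, and 0.0196 with an estimated correlation) and glycolysis 14 of 20 (median 0.56, camera adjusted p = 6.08e-13, and 0.113 with an estimated correlation). Pyruvate dehydrogenase and citrate cycle genes had 11 higher of 22 (median 0.32, camera adjusted p = 8.65e-11, and 0.681 with an estimated correlation) and oxidative phosphorylation 14 higher and 1 lower of 71 (median 0.22, camera adjusted p = 7.83e-11, and 0.744 with an estimated correlation). In branched-chain amino acid breakdown 7 were higher and 1 lower of 24 (median 0.24, camera adjusted p = 0.0012, and 0.744 with an estimated correlation), not independent evidence of direction. Interferon response had 7 lower of 17 (median -0.69, camera adjusted p = 2.93e-07, and 0.681 with an estimated correlation). Medians were lower for macrophage markers (0 called of 16, median -0.36, camera adjusted p = 0.0133), cell cycle (0 of 18, -0.43, 0.0478) and unfolded protein response (1 lower of 16, -0.16, 0.0492). They were higher for white adipocyte markers (3 higher of 9, 0.27, 0.0478), the thermogenic list (4 higher and 1 lower of 20, 0.16, 0.0492) and fatty acid oxidation (1 higher and 1 lower of 20, 0.098, 0.0492). Each had adjusted p = 0.744 with an estimated correlation. The thermogenic and fatty acid oxidation medians turned to -0.0156 and -0.024 with the one-read level covariate. Ucp1 did not differ (-0.034, SE 0.119, adjusted p = 0.893), nor did Gipr (-0.51, SE 0.189, adjusted p = 0.0829). Over the 6 comparisons between groups, cholesterol synthesis alone passed camera with an estimated correlation, and only for PairFedVehicle against Vehicle and LAGIPRA against PairFedVehicle.

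**Figure D4:**
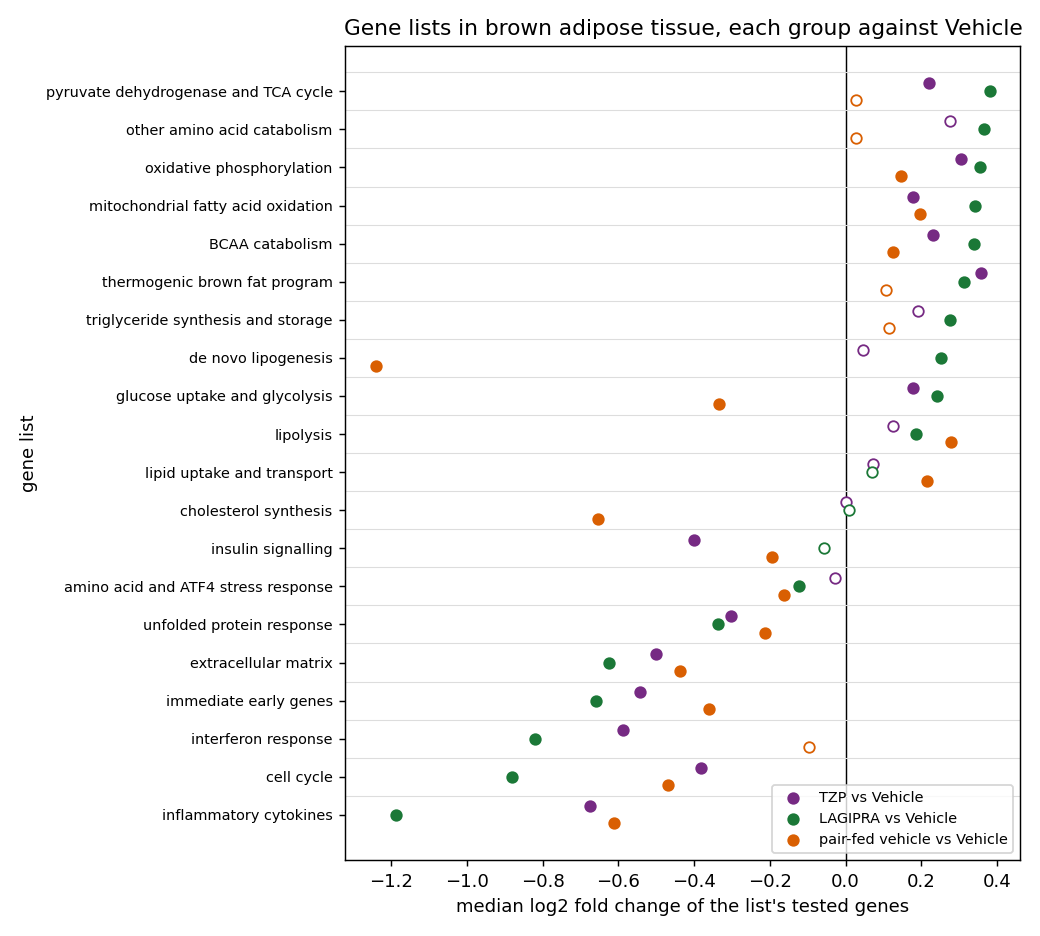
Median log2 fold change of 20 gene lists in TZP, LAGIPRA and PairFedVehicle against Vehicle. Filled symbols mark lists with a camera adjusted p below 0.05.

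The 3 treated groups were set side by side to ask how far their differences from Vehicle were shared. Of the genes that passed, 1048 were higher in both TZP and LAGIPRA (175.8 by chance), 357 lower in both (89.7 by chance) and 0 opposed. TZP and PairFedVehicle shared 358 higher (100.2 by chance) and 210 lower (65.2 by chance), with 34 opposed. LAGIPRA and PairFedVehicle shared 269 (74.5 by chance) and 134 (31.7 by chance), with 27 opposed. All 3 differences use the same Vehicle samples, which by itself makes them alike. Across genes, which are not independent replicates, r was 0.669 for TZP with LAGIPRA, where simulated effects of zero with the shared control gave a mean of 0.509 (0.0102 to 0.876 over 100 draws). The covariance was 0.114 against a simulated mean of 0.0341 and a simulated highest of 0.111, and r fell to 0.424 with the Vehicle samples divided between the comparisons. TZP with PairFedVehicle gave r = 0.483 against 0.493 simulated, and a covariance of 0.0728 that lay within the simulated values (mean 0.0333, highest 0.0866). LAGIPRA with PairFedVehicle gave r = 0.457 against 0.492 simulated, and its covariance of 0.0650 also lay within the simulated values (highest 0.0708). The counts by chance above do not allow for the shared control.

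The last question was whether TZP minus PairFedVehicle matched LAGIPRA minus Vehicle, as it would if restricted feeding and GIP receptor agonism simply added up in TZP. It did not for 465 genes, 200 with a positive and 265 with a negative departure. LAGIPRA and tirzepatide are different molecules, and the group that set the pair-fed amount is not known, so this test is descriptive. Cholesterol synthesis departed upward in 8 of 22 (15 when adjusted over the list alone; median 0.53, camera adjusted p = 2.53e-12, and 0.0347 with an estimated correlation) and lipogenesis in 6, with 1 downward, of 18 (median 0.90, camera adjusted p = 2.76e-06, and 0.382 with an estimated correlation). Fatty acid oxidation (0 up, 1 down of 20; median -0.36, camera adjusted p = 1.42e-05, and 0.387 with an estimated correlation) and lipolysis (0 up, 3 down of 10; median -0.27, camera adjusted p = 2.1e-05, and 0.333 with an estimated correlation) departed downward. The branched-chain amino acid genes had 0 up and 2 down of 24 (median -0.27, camera adjusted p = 1.03e-05, and 0.387 with an estimated correlation), not independent evidence of direction. Large medians were also those of cytokines and chemokines (1.28, camera adjusted p = 2.86e-05, and 0.333 with an estimated correlation), cell cycle (0.997, 2.76e-06, estimated 0.387) and erythroid markers (-1.30, 0.00188, estimated 0.387). Endothelial markers departed downward in 4 of 11 (-0.41, 5.58e-05, estimated 0.333), and macrophage markers had 0 single calls by limma with a median of 0.50 (0.00156, estimated 0.426). Cholesterol synthesis did not pass in TZP against Vehicle, and neither did lipogenesis, but TZP libraries differed in fat synthesis: Fasn was 10.785, 11.473 and 11.273 in TZP 3, 5 and 6, below the lowest Vehicle sample (12.288), and 12.852, 13.387 and 13.171 in TZP 1, 2 and 4. The count was 289 without Vehicle 1, 241 without Vehicle 6, 270, 278 and 269 without LAGIPRA 3, 4 and 5, 743 without TZP 1, 277 without TZP 5, 297 without TZP 6 and 294 without PairFedVehicle 1.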

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

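The tests of explanations in this part, the regroupings of samples included, had their expectations written down only after the results were seen. A value was set apart when 1 sample of a group of 6 stood far outside the range of the other 5. This happened in 47 of 980 groups, 4.80%, over 210 genes, 33 lists and 2 library measures, and about 1 group in 20 would give such a value by chance. The values that follow are single samples, without a test of their cause unless one is given.

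Skeletal muscle transcripts were the plainest case, and muscle carried along with the depot is a plain reason. The muscle list mean was -5.68 in TZP 3 (others -0.23 to 2.32) and -1.04 in LAGIPRA 4 (1.13 to 2.10). Myosin genes went with it: in TZP 3 Myh1 was 0.51 (others 6.21 to 9.25) and Myh4 0.23 (7.78 to 10.14), and in PairFedVehicle 5 Myh4 was 0.16 (8.02 to 12.10). In LAGIPRA 4 Myh1 was 6.73, Myh2 4.88 and Myh4 7.21. The creatine and calcium cycling list, which contains genes that muscle also expresses, was -0.44 in LAGIPRA 4 (others 0.37 to 0.65).

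Blood content is a plain reason for LAGIPRA 1, where the erythroid list was 1.27 (others 0.40 to 0.71), Alas2 7.67 (6.73 to 6.99) and Hbb-bs 15.62 (14.74 to 14.85). In Vehicle 5 low values of dividing cells and stroma came together: Kif11 2.15 (others 3.91 to 4.58), Top2a 3.44 (4.94 to 5.71), Mrc1 6.41 (7.30 to 7.67) and Pdgfra 3.84 (4.68 to 4.92), as fewer such cells in the piece taken would give. In TZP 3 Mki67 was 4.80 (others 3.39 to 3.92). The nerve marker list was -0.47 in Vehicle 6 (others -0.04 to 0.16), as less nerve in the piece would give.

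Depth and length measures stood apart in 2 libraries. The value of 1 read was 1.55 in Vehicle 4 (others 0.853 to 1.10), a shallower library if that value stands for depth. In it Gipr, close to the lowest values, was 3.50 (others 2.81 to 2.99) and Nupr1 9.36 (9.64 to 9.79). The length slope was 0.0505 in LAGIPRA 2 (others -0.00596 to 0.00874), where Gsk3b was 5.20 (4.85 to 4.97) and Wfdc21 6.93 (5.68 to 6.13).

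PairFedVehicle 1 held 6 values, the most of any library: Thrsp 13.26 (others 12.09 to 12.44), Dbp 4.80 (5.64 to 5.94), Dlst 9.73 (9.25 to 9.38), Slc27a2 9.02 (8.20 to 8.46), Acsm3 7.21 (6.60 to 6.81) and Tie1 7.86 (7.56 to 7.66). A different time since the last meal or of sampling is a plain reason for the lipogenic gene and the clock gene, and was not tested. In PairFedVehicle 4 Mir7011 was 4.03 (others 4.86 to 5.36), Plxna1 6.59 (6.07 to 6.17) and Sel1l 5.99 (5.60 to 5.69). In PairFedVehicle 5 Cxcl2 was 4.24 (2.614 to 3.22), and in PairFedVehicle 6 Mir5114 was 5.83 (5.26 to 5.40) and the ATF4 list 0.26 (-0.19 to -0.04). Chance is a sufficient reason for these.

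The remaining values were spread over genes without a common theme, for which chance is also a sufficient reason. In LAGIPRA 3 Bmp8b was 2.64 (others 3.85 to 4.35). In LAGIPRA 5 Bst2 was 6.65 (7.15 to 7.32), Grb14 7.76 (7.52 to 7.58) and Timp1 4.08 (5.16 to 5.77), and in LAGIPRA 6 Cox8b was 15.99 (16.21 in all 5 others). The 5 equal values of Cox8b are what quantile normalization gives a gene of equal rank, so the difference may be a step in rank. TZP 1 had C1qa at 9.11 (9.74 to 10.08) and Irf7 at 5.86 (6.14 to 6.24), and TZP 2 Cxcl10 at 4.36 (4.97 to 5.33). TZP 4 had Gcdh at 6.85 (6.42 to 6.56), Hsd17b10 at 9.01 (8.68 to 8.77) and Tmem79 at 8.24 (7.37 to 7.60). Apart from single samples, 465 genes departed from additivity, a difference between groups that was tested. Lipogenesis (6 upward) and cholesterol synthesis (8 upward) make up a small part of them, and no plain reason was found for the rest. Genes with a negative departure had longer transcripts (median 3065 bases, against 2052.5 for a positive one). A part played by the length pattern of TZP libraries 3 to 6 was not tested.

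Long genes were lower in TZP libraries 3 to 6, for which an effect of tirzepatide itself was not tested and stays open. GC content is excluded: TZP minus Vehicle was -0.113 with GC in the same regression (exact permutation p = 0.00216, two-sided). Library depth, as far as the one-read level stands for it, is excluded, because 14 other libraries of similar one-read level had slopes no lower than -0.00596. Of the TZP calls 46.6% were made again after the length correction. That correction may leave length effects, so length stays open. Another property of these libraries that goes with the slope, such as RNA integrity, cannot be told apart from the treatment: 4.05% of the genes were called again with the slope as covariate, and what keeps it open is that the slope itself differs with the group.

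Skeletal muscle transcripts were low in Vehicle 1, TZP 3 and PairFedVehicle 5. Muscle carried along with the depot in the other libraries was not tested. Treatment alone cannot account for it, because the 3 low libraries lay in 3 groups and Vehicle 1 (1.12) had the treatment of the other Vehicle samples (up to 9.58). Muscle means within Vehicle ranged over 8.45 log2, against a largest difference of 1.62 between group means. That range is set by Vehicle 1 itself, so it adds no separate evidence.

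Mitochondrial lists were higher in LAGIPRA than in Vehicle. Transcript length, as far as corrected for, is excluded as the whole cause, with at least 83.02% of each of 4 medians kept. So is muscle, with at least 95.1% kept with the muscle and lymphocyte covariates. Single calls fell all the same, from 54, 17, 14 and 16 in oxidative phosphorylation, citrate cycle, fatty acid oxidation and branched-chain lists to 33, 11, 3 and 9 with the length correction and to 27, 9, 5 and 8 with the covariates. A lower share of all other cells would lower macrophage and endothelial markers alike, yet macrophage minus endothelial markers differed by -0.71 (exact permutation p = 0.0281, two-sided). This argues only against an equal fall of all other cells. A smaller share of macrophages or other single cell types was not tested and stays open. Library depth, or whatever else sets the one-read level, cannot be told apart from treatment. With the one-read level covariate at least 44.0% of each median was kept. The lists passed camera (highest adjusted p = 0.00631), but 0 single members were called. What keeps it open is that the one-read level itself was higher in LAGIPRA.

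Regrouping asked whether chance divisions of the samples give as many genes. As many or more were called in 1 of the 100 splits for TZP against Vehicle (3805, highest other 1255), in 1 of the 100 splits for PairFedVehicle against Vehicle (1487, highest other 1439), TZP against PairFedVehicle (2832, highest other 2070), LAGIPRA against PairFedVehicle (2046, highest other 534) and additivity (465, highest other 11), the real division being that 1. In these 5 no other division drawn called as many genes. Only 100 of the 462 possible divisions between 2 groups were drawn, so chance is not excluded. For LAGIPRA against Vehicle it was 2 of the 100 splits (2370, highest other 3393) and for TZP against LAGIPRA 3 of the 100 splits (69, highest other 916). A division that calls more genes than the real one, and several times more in TZP against LAGIPRA, may reflect a structure of the samples other than the groups. Such a structure was not tested, and no conclusion about chance is drawn for these comparisons.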

How the results depend on the processing

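Thresholds. With adjusted p under 0.01 the counts were 1620 for TZP against Vehicle, 280 for LAGIPRA against Vehicle, 601 for PairFedVehicle against Vehicle, 1193 for TZP against PairFedVehicle, 0 for TZP against LAGIPRA, 900 for LAGIPRA against PairFedVehicle and 96 for additivity. With a fold of at least 1.5 they were 1476, 772, 684, 1196 and 767 in the same order without TZP against LAGIPRA and additivity.

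Models. TZP against LAGIPRA, 69 genes in the primary test, had 15 with no filter and 15 with no variance trend. With only the groups compared the counts were 2514 for TZP against Vehicle, 1503 for TZP against PairFedVehicle and 3 for TZP against LAGIPRA. That fit uses the spread of the groups compared and not the spread pooled over all groups. Array weights raised LAGIPRA against Vehicle to 4783, TZP against LAGIPRA to 1071, LAGIPRA against PairFedVehicle to 3260 and additivity to 1066. A second quantile normalization, a robust variance prior and leaving out the lowest 50% moved no count by more than 1.5-fold.

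Replicate block. With the replicate number as a block TZP against LAGIPRA had 23 genes. The other counts were 3549 for TZP against Vehicle, 1921 for LAGIPRA against Vehicle, 1299 for PairFedVehicle against Vehicle, 2625 for TZP against PairFedVehicle and 1752 for LAGIPRA against PairFedVehicle. Correlations across genes between samples of equal number averaged 0.103 in TZP and Vehicle (unequal numbers -0.0206) and 0.180 in LAGIPRA and Vehicle (-0.0355), but -0.114 in PairFedVehicle and Vehicle (0.0240), -0.138 in TZP and PairFedVehicle (0.0278), 0.00827 in TZP and LAGIPRA (-0.00161) and -0.107 in LAGIPRA and PairFedVehicle (0.0218). The own number was the best match in 2, 3, 0, 1, 0 and 0 of 6, and in no pair of groups did every correlation exceed 0.1, so the numbers were not taken to pair the samples.

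Muscle and lymphocyte means as covariates left 1043 genes for LAGIPRA against Vehicle and 20 for TZP against LAGIPRA, where the skeletal muscle list had a median of 0.1413.

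List tests. The list of branched-chain amino acid breakdown did not pass with an estimated correlation: 0.2308 in TZP against Vehicle (adjusted p = 0.692), 0.339 in LAGIPRA against Vehicle (0.353), 0.1264 in PairFedVehicle against Vehicle (0.709) and -0.1209 in TZP against LAGIPRA (0.849). With fry 0.1264 in PairFedVehicle against Vehicle (0.182) and -0.1209 in TZP against LAGIPRA (0.533) did not pass. Of the lists called by camera, an estimated correlation kept 0 of 16, 0 of 19, 1 of 18, 0 of 8, 0 of 13 and 1 of 13 over the 6 comparisons, and fry kept 10, 14, 7, 4, 3 and 6.

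Correlations across genes. With only genes past the threshold in either comparison, r for TZP and LAGIPRA was 0.7822. With the Vehicle samples split 3 and 3 it was 0.4244, and for TZP and PairFedVehicle 0.2315.

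Libraries left out. LAGIPRA against Vehicle ran from 945 (without LAGIPRA 5) to 3819 (without Vehicle 5), additivity from 241 (without Vehicle 6) to 743 (without TZP 1) and TZP against LAGIPRA from 0 (without LAGIPRA 3) to 1088 (without TZP 2). The branched-chain list ran from -0.171 (without TZP 1) to -0.0578 (without TZP 6) in TZP against LAGIPRA and from 0.0409 (without TZP 4) to 0.1561 (without PairFedVehicle 1) in TZP against PairFedVehicle. Other counts stayed within 1.5-fold: 2739 to 4494, 1049 to 1620, 2018 to 3181 and 1404 to 2472.

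The settings that follow were added after the results were seen. Correction for transcript length kept 1772 of the TZP against Vehicle calls (46.6%), 1693 for LAGIPRA against Vehicle (71.4%), 1088 for PairFedVehicle against Vehicle (73.2%), 1813 for TZP against PairFedVehicle (64.0%), 48 for TZP against LAGIPRA (69.6%) and 1776 for LAGIPRA against PairFedVehicle (86.8%).

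Length slope as a covariate left 203 genes in TZP against Vehicle, 970 in TZP against PairFedVehicle and 0 in TZP against LAGIPRA. Per3 had 0.048 in TZP against Vehicle. Breakdown of branched-chain amino acids was 0.1959 in TZP against PairFedVehicle (adjusted p = 0.00413) and -0.0125 in TZP against LAGIPRA. Insulin signalling was 0.221 in TZP against Vehicle, 0.023 in PairFedVehicle against Vehicle, 0.1396 in TZP against PairFedVehicle and 0.0215 in TZP against LAGIPRA. Fatty acid oxidation was 0.1042 in TZP against PairFedVehicle and 0.001 in TZP against LAGIPRA, where the thermogenic list was 0.1966. With length slope and muscle as covariates there were 243, 1002 and 0 genes and Per3 had 0.038. The branched-chain list was 0.1973 (adjusted p = 0.00483) and -0.008, insulin signalling 0.2203, 0.0243 and 0.1352, and fatty acid oxidation 0.1058 and 0.016. In TZP against LAGIPRA the thermogenic list was 0.2129, triglyceride synthesis 0.0695 and skeletal muscle 0.0694.

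Only TZP libraries 1 and 2. TZP against Vehicle had 817 genes (544 higher, 273 lower), TZP against PairFedVehicle 1031, TZP against LAGIPRA 2 and additivity 151. For branched-chain amino acid breakdown the median was 0.2563 in TZP against PairFedVehicle (adjusted p = 0.000119) and 0.0487 in TZP against LAGIPRA. Insulin signalling was 0.0112 in TZP against Vehicle. In TZP against PairFedVehicle insulin signalling was 0.1998, fatty acid oxidation 0.1826, glucocorticoid response 0.3705, cytokines -0.539, cell cycle -0.5357 and the Pde3b change 0.101. In TZP against LAGIPRA insulin signalling was 0.0157, fatty acid oxidation 0.0818, thermogenic 0.2439, pyruvate dehydrogenase and citrate cycle 0.009, oxidative phosphorylation 0.0113, triglyceride synthesis 0.171, cAMP signalling 0.0046 and cell cycle -0.1185.

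Without the 3 libraries lowest in muscle, LAGIPRA against Vehicle had 1233 genes, TZP against LAGIPRA 23 and additivity 291. The branched-chain list was -0.0818 in TZP against LAGIPRA (adjusted p = 0.0822).

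One-read level as a covariate gave 2496 genes in TZP against Vehicle (809 higher, 1687 lower), 45 in LAGIPRA against Vehicle (25 higher, 20 lower), 268 in TZP against LAGIPRA and 1258 in LAGIPRA against PairFedVehicle. Breakdown of branched-chain amino acids was 0.0525 in TZP against Vehicle (adjusted p = 0.244) and -0.0126 in TZP against PairFedVehicle. Lipogenesis was -0.1261 in TZP against Vehicle (adjusted p = 0.0326) and -0.075 in LAGIPRA against Vehicle, and cell cycle 0.0852 in TZP against Vehicle. In LAGIPRA against PairFedVehicle the thermogenic list was -0.0156 and fatty acid oxidation -0.024. The cause of these shifts was not tested beyond what is given under the explanations.

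Not run were a pseudocount on linear values, count models and a test of raw counts, because the values are normalized logarithms. Depth limits what can be said of weakly expressed genes such as Gipr.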

Other observations

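The tests drawn on here were chosen only after the results were seen. The GIP receptor agonist and tirzepatide left brown fat with more transcripts of oxidative phosphorylation, 54 and 45 genes higher of 71, and pair feeding with 4 (adjusted p = 0.353, 0.588 and 0.709 with an estimated correlation). Compared directly with PairFedVehicle, fewer members passed: 14 higher and 1 lower in LAGIPRA, and 8 higher and 1 lower in TZP. Neither comparison passed with an estimated correlation (adjusted p = 0.744 and 0.938). Library depth, or whatever else sets the one-read level, may account for part of the LAGIPRA rise. With the one-read level covariate the share of the median that remained was as low as 44.0% among its 4 mitochondrial lists, and 0 single members were called. The one-read level differed from Vehicle in TZP as well (exact permutation p = 0.0411, adjusted 0.117). With it as a covariate, 7 of the 16 lists called in TZP against Vehicle kept their calls. Pair feeding lowered the lists of lipogenesis (adjusted p = 0.185 with an estimated correlation) and cholesterol synthesis (0.00423). Under tirzepatide lipogenesis did not pass, except as a fall with the one-read level covariate (-0.1261, adjusted p = 0.0326). The TZP libraries were divided, so this is no sign of a level equal to Vehicle. The list mean lay above all Vehicle samples in TZP 1, 2 and 4 and below all of them in TZP 3, 5 and 6. The cause of these differences was not tested.

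The list median of branched-chain amino acid breakdown was higher in each of the 3 groups against Vehicle. Of its 24 genes 16 were called in LAGIPRA, 7 in TZP and 5 in PairFedVehicle. The list did not pass with an estimated correlation (adjusted p = 0.353 in LAGIPRA, 0.692 in TZP and 0.709 in PairFedVehicle). In TZP the list mean exceeded all Vehicle samples only in libraries 1, 2 and 4. The TZP call was also lost with the one-read level covariate (0.0525, adjusted p = 0.244). Against PairFedVehicle it passed for LAGIPRA (0.24; adjusted p = 0.744 with an estimated correlation, 0.208 with fry) but not for TZP (0.09). TZP libraries 1 and 2 alone gave 0.256 there. The list mean did not follow the length slope throughout, as TZP 4, with a slope of -0.0938, had a mean of 0.230. Values of 1 read were 1.74, 1.88 and 1.84 in TZP 1, 2 and 4. In TZP 3, 5 and 6 they were 1.44, 1.23 and 0.948. With the one-read level covariate the median against PairFedVehicle was -0.0126, in the other direction. Whether tirzepatide raised this pathway beyond restricted feeding stayed open, as the median depended on the libraries and covariate used.

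Ucp1 rose by 0.41 to 0.50 log2 against Vehicle in all 3 groups, and no difference passed between TZP and PairFedVehicle (0.054). As its values repeat between libraries, these sizes may be steps in rank among the highest genes rather than measured folds. All 3 calls were lost after the length correction (adjusted p = 0.0606 in TZP, 0.0816 in LAGIPRA and 0.0661 in PairFedVehicle). The LAGIPRA call was also lost with the one-read level covariate (0.434, adjusted p = 0.134), against 0.411 in the primary test. The PairFedVehicle call was lost without the 3 libraries lowest in muscle (0.409, adjusted p = 0.0805), against 0.445. The size of the TZP rise depended on how transcript length was handled, with 0.365 after the length correction and 0.757 with the length slope as a covariate.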
